A study of Triticum aestivum with 36 samples.

How the data were processed

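RNA sequencing was carried out on leaves of 2 cultivars of bread wheat (Triticum aestivum), Hereward and Robigus. Seedlings at the three-leaf stage were inoculated with the fungus Pyrenophora tritici-repentis (Ptr), which causes tan spot, or mock-inoculated, per the labels' protocols. The isolate was described as positive for toxA, a gene for a secreted necrotrophic toxin. Plants were grown in compost in controlled growth rooms and each pot counted as 1 replicate, with pots placed at random in the room. Leaves were collected before treatment (0 h) and at 48 h and 96 h after it, from 4 sets of plants: Hereward Ptr, Hereward mock, Robigus Ptr and Robigus mock. The 36 libraries therefore form 12 groups of 3 pots. At 0 h the Ptr and mock sets were both untreated. RNA was extracted with a plant column kit that included DNase digestion, and libraries followed the standard Illumina protocol, per the labels' protocols. The series' title names a resistant and a susceptible line, and which cultivar is which was not given in the sources used here.

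The deposited tables held a normalized count and an FPKM value per transcript and library. Reads were quantified with Salmon 1.3.0, and DESeq2 was also used, per the submitters' processing notes. The reference transcripts, the read filters and the step each tool carried out were not given in the sources used here. The deposited normalized counts are a non-negative signal scaled by the authors, not raw read counts. Only 1.71% to 9.77% of the values per library came out as whole multiples of its smallest nonzero value (tolerance 0.01). Estimated counts need not be whole and that value need not be 1 read, so this check does not settle the scaling. Whole reads were not recovered, and read depth per library stays unknown here. No count model was therefore run. The deposited FPKM value was the normalized count times 1 constant per transcript, with a relative spread of that ratio of at most 2.6e-07 over the libraries. The FPKM table thus carries the same scaling between libraries and is no independent measurement.

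The tables listed 42276 transcripts of 36275 gene models, of which 4976 had more than 1 transcript and at most 8. The filter fixed before the data were examined (a normalized count of at least 10 in at least 3 libraries) removed 0 transcripts. The smallest third-highest value of any transcript was 68.7, so the alternative minimum of 50 removed none either and neither filter could be assessed. The tables thus hold transcripts that had already passed some minimum. Sums of normalized counts per library ran from 13.9 to 28.9 in units of 1000000. Medians per library ran from 136.4 to 165 normalized counts, and 2519 to 8121 transcripts per library were listed at 0. No pair of libraries held identical values, and the highest Pearson correlation between any pair across transcripts was 0.912.

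Identifiers name a chromosome and a gene model number but no gene. The files pair them with no gene names or descriptions, and 0 of them matched the 155467 entries of the RefSeq gene table that was searched. The functional gene lists fixed before the data were examined were therefore not tested, and no coordinates are given. At most 2 identifiers that rose and 2 that fell are named per contrast: those with the largest change among transcripts with an adjusted p under 0.05, a mean of at least 50 in the higher group and, where 2 sets of libraries were compared, every library of one set beyond every library of the other.

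Differences were tested with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a trended and robust variance prior, all 36 libraries in 12 groups sharing 1 estimate of the spread. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all transcripts of a contrast, and a transcript was called at an adjusted p under 0.05. All adjusted p-values quoted are from these limma fits. Log2 changes are on the log2(normalized count + 1) scale, which understates changes of low transcripts. An exact 0 in estimated counts can reflect the split of reads between similar transcripts, so values at 0 are described as listed at 0 and no fold of a single transcript is given against a group at 0. Medians over lists include such transcripts and depend on the pseudocount, so the medians of called lists are also given without them. The differences between responses of 2 transcripts with such groups are given as fitted values only. Transcripts of 1 gene model, and the near-identical copies on the A, B and D subgenomes of hexaploid wheat, can share reads, and how such reads were divided between them was not given in the sources used here. Contrasts were Ptr against mock in each cultivar at 48 h and 96 h, the difference of that response between cultivars and between times, the cultivars against each other at 0 h, the Ptr against the mock sets at 0 h, and mock plants at 48 h and 96 h against 0 h over both cultivars. The Ptr against mock contrasts share no libraries with one another. Pots came from 1 experiment. P-values rest on a spread per transcript estimated over all 12 groups, not on that of the groups compared. Pooled SDs within groups ran from 0.937 (Robigus mock at 0 h) to 2.08 (Robigus Ptr at 48 h). P-values can thus be too small where pots scattered more and too large where they scattered less.

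The same tests were repeated with other pseudocounts (0.5 and 5), the FPKM table, trimmed-mean and quantile scaling, a variance model with neither trend nor robust step, weights per library, a minimum change of 1 on the log2 scale, a fit of only the groups compared, a block for the replicate number and leaving out each library. Another 4 repeats were chosen after the data were seen: values summed per gene model, removal of a trend with transcript length, the difference between the sets at 0 h taken as baseline, and the cultivars compared over the mock sets at 0 h alone. The baseline repeat subtracts a second pair of groups, so its standard errors are larger. Differences between responses, which have the same form, had a median standard error of 0.838 against 0.593 for Ptr against mock. It can thus call fewer transcripts even where the sets were alike. The 4 Ptr against mock tests were checked on simulated values in which 200 of 42276 transcripts were changed by known amounts, 50 at each of 4 sizes. For Hereward at 48 h, 0% of changes of 1 (log2), 22% of 2, 68% of 4 and 92% of 8 were called, with 7 false calls. For Robigus at 48 h, these shares were 6%, 54%, 72% and 84%, with 3 false calls. For Hereward at 96 h they were 6%, 38%, 66% and 84%, with 4 false calls, and for Robigus at 96 h 2%, 34%, 48% and 88%, with 7. The simulated spread of a transcript was the same in every group, so these shares differ between contrasts by the draw alone and do not compare the cultivars or times. In this simulation most changes of 1 were thus not resolved. The adjusted cutoff is less strict where many more transcripts change, as in Hereward at 48 h with 17.2% called. The shares therefore do not carry over to the real contrasts. Figures were drawn with Python 3.11.15.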

Results

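Expression was measured in leaves of the wheat cultivars Hereward and Robigus before inoculation and 48 h and 96 h after inoculation with the tan spot fungus Pyrenophora tritici-repentis (Ptr) or after mock inoculation. Each of the 12 groups held 3 pots. The values are normalized counts of 42276 transcripts, and their sums per library, in units of 1000000, ran from 15.2 to 23.5 in the 12 inoculated libraries and from 13.9 to 28.9 in the 24 others. At 48 h the mean sum fell by 8.73 of these units from mock to inoculated plants in Hereward and fell by 6.03 in Robigus (two-sided exact permutation p = 0.1 for each, the smallest value 3 against 3 pots allow). At 96 h it fell by 4.9 in Hereward (exact p = 0.1) and fell by 1.97 in Robigus (exact p = 0.2). Sequencing depth is unknown, so a value at 0 sets no limit on abundance. Agreement between pots of a group was uneven, with mean Pearson correlations across transcripts of 0.491 to 0.884 per library. It was lowest for Robigus Ptr replicate 1 at 48 h, which also had the most transcripts listed at 0, 8121 against 2519 to 5875 in the other libraries.

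In Hereward at 48 h, inoculation was followed by changes in 17.2% of the transcripts: 3697 were higher and 3558 were lower than in mock plants. The median change of those called was 2.47 (log2) among the higher and −1.997 among the lower (2.32 and −1.98 without transcripts listed at 0 in a whole group), and 1558 rose by at least 3 while 726 fell by at least that much. Most risers already had a value in mock leaves, at a median of 67.3 normalized counts against 369 after inoculation, and 175 of them (4.73%) were listed at 0 in all 3 mock pots. The largest rises included TraesCS7B02G253600.1, listed at 0 in every mock pot and at 4488, 1883 and 53826 in the inoculated pots (limma, adjusted p = 8.4e-06), and TraesCS5A02G004800.1, also listed at 0 in mock and at 2961, 1425 and 6033 after inoculation (adjusted p = 8.8e-07). The largest falls were in single isoforms: TraesCS7D02G288700.2 was at 169, 1103 and 2166 in mock and listed at 0 in all 3 inoculated pots (adjusted p = 0.016), and TraesCS3D02G391700.2 was at 331, 839 and 923 against 0 (adjusted p = 0.032). All 3 inoculated pots lay above all 3 mock pots for 14.8% of the transcripts and below them for 10.9%, where chance gives 5% in each direction. The untreated Hereward sets at 0 h were apart about as often, with 10.3% above and 14.9% below, so these shares alone do not mark inoculation. The named falls in TraesCS7D02G288700.2 and TraesCS3D02G391700.2 lost their calls under 5 and 6 of 20 alternatives. Neither transcript had a lower mean log2 level after inoculation elsewhere. The changes at 96 h in Hereward and at 48 h and 96 h in Robigus were 2.07, 5.92 and 1.05 for the first. They were 0.9, 3.13 and 0.88 for the second. Both were also listed at 0 in some untreated pots at 0 h. With only these 6 libraries in the fit 70 transcripts were called, with weights per library 13249, and with the difference between the sets at 0 h subtracted 4400. The last repeat has larger standard errors, so its lower count does not by itself mark unlike sets. The count was 1929 without Ptr replicate 3, 4286 without Ptr replicate 1 (1975 higher, 2311 lower) and 4561 without mock replicate 2 (2160 and 2401), and it was 5012 higher and 5588 lower without Ptr replicate 2.

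In Robigus at 48 h, 295 transcripts were called higher and 33 lower after inoculation, together 0.776% of those tested. This balance changed with single libraries: without Ptr replicate 3 there were 454 higher and 1474 lower, and without Ptr replicate 2 there were 664 and 772. The rises had a median of 5.96 (log2; 5.69 without those listed at 0 in a whole group). They took transcripts from a median of 3.31 normalized counts in mock to 291, with 49 (16.6%) listed at 0 in all 3 mock pots. With so few calls only large changes pass. The same transcripts had a median of 6.02 in Hereward, so their size does not mark a stronger response in Robigus. TraesCS5D02G488700.1 rose by 12.06 ± 1.06 (SE, n = 3 pots per group; limma, adjusted p = 1.5e-07), from 0.733 ± 1.27 (SD) to 9412 ± 9585. TraesCS3A02G260200.1 was listed at 0 in the mock pots and at 2610, 329 and 8049 in the inoculated ones (adjusted p = 1.5e-07). Among the falls, which had a median of −3.78 (−3.64 without the 1 listed at 0 in a whole group), TraesCS5D02G063700.2 fell by 7.37 ± 1.79 (adjusted p = 0.046), from 759, 172 and 762 to 0, 0 and 21, and TraesCS2D02G423500.3 fell by 7.27 ± 1.60 (adjusted p = 0.023), from 401, 858 and 501 to 0, 0 and 46. Of the 33 falls, 25 (75.8%) were also called when the transcripts of a gene model were summed, against 293 of the 295 rises (99.3%). The named falls lost their calls under 11 and 8 of 20 alternatives. With only these 6 libraries in the fit no transcript was called (limma; 0, beside 5995 at an unadjusted p under 0.05 in the fit of all libraries), with weights per library 184, and with the sets at 0 h as baseline 43. The count was 118 without Ptr replicate 1, 1436 without Ptr replicate 2, 1928 without Ptr replicate 3, 180 without mock replicate 1 and 128 without mock replicate 3.

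**Figure D1:**
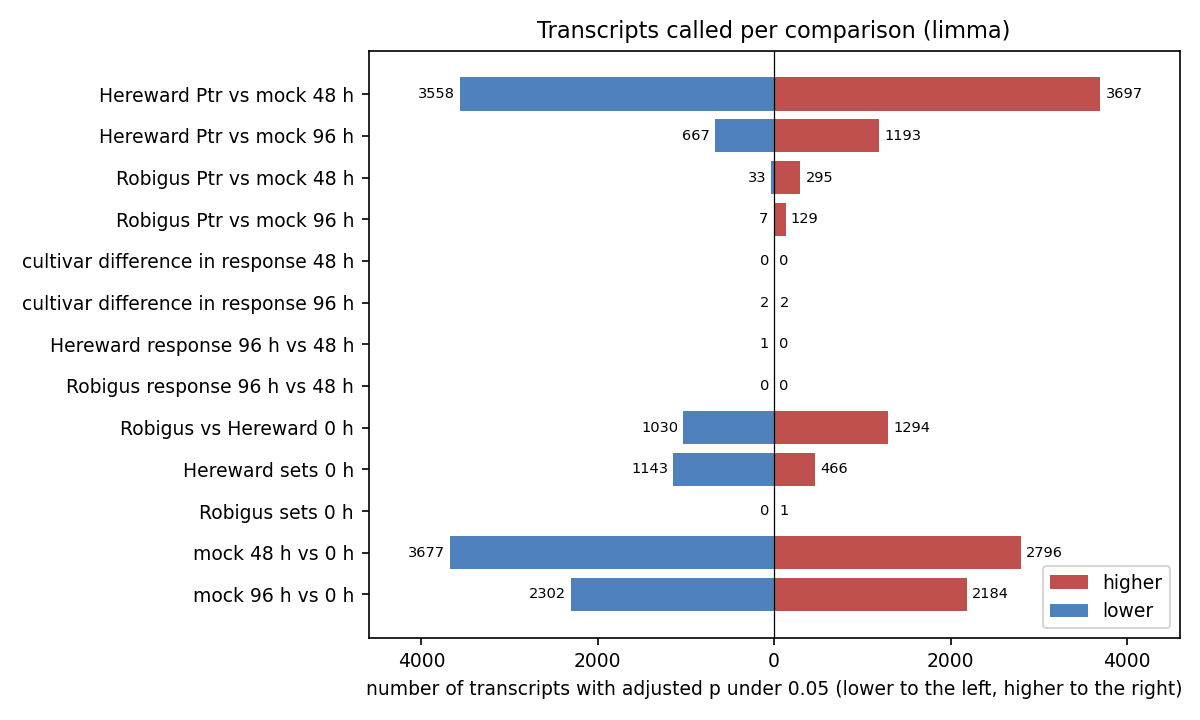
Number of transcripts called higher (red, right) or lower (blue, left) in each of the 13 contrasts by limma at an adjusted p under 0.05, with 3 pots per group. Hereward had 3697 higher and 3558 lower transcripts at 48 h, and Robigus 295 and 33.

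Most of what rose in Robigus at 48 h had also risen in Hereward. Of the 295 Robigus rises, 267 (90.5%) were called higher in Hereward, where independent lists of these sizes would share 25.8, and 0 transcripts were called in opposite directions in the 2 cultivars at 48 h. These 267 transcripts belong to 265 gene models and are referred to as the shared rises. The falls overlapped less, with 8 of the 33 (24.2%) called lower in Hereward and 2.78 expected. In the other direction, the 3697 Hereward rises had a median change of 0.99 in Robigus, 90.4% of them upward, and the 3558 falls a median of −0.63, 89.6% of them downward. Across transcripts, which are not independent replicates, the changes in the cultivars correlated with a Pearson r of 0.36. Averaged over the shared rises, expression on the log2 scale was 8.28 ± 0.485 (SD, n = 3) in inoculated Hereward and 8.20 ± 1.10 in inoculated Robigus at 48 h, against 2.22 ± 0.308 and 2.32 ± 0.894 in mock. The transcripts were chosen as higher in both cultivars in these same libraries, so this gap from mock follows from the choice. The shared rises were spread over the subgenomes, with 84 on A, 73 on B and 99 on D (0.606%, 0.528% and 0.702% of the transcripts tested there) and 11 on unplaced sequence. The overlap was 143 with weights per library. It was 34 with the sets at 0 h as baseline, a repeat with larger standard errors.

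**Figure D2:**
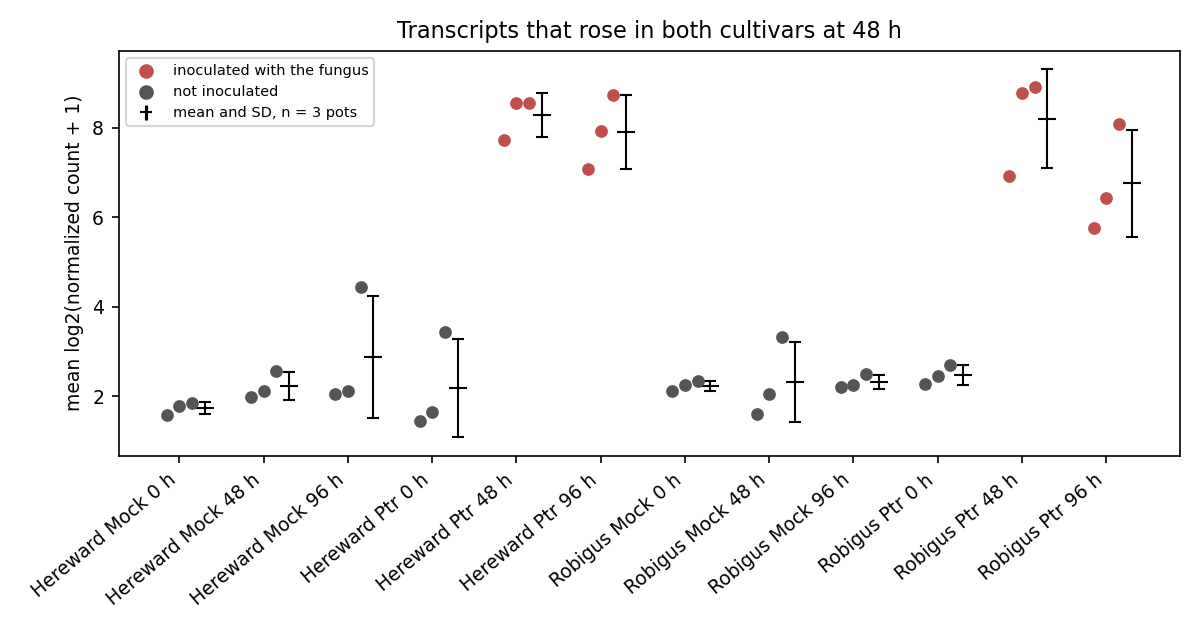
Mean log2(normalized count + 1) of the transcripts that rose in both cultivars at 48 h, 1 point per library, with the mean and SD of 3 pots per group. The 12 inoculated libraries lie between 5.76 and 8.91 and the 24 uninoculated ones between 1.44 and 4.44; the transcripts were chosen on the 48 h libraries.

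At 96 h Hereward had 1193 transcripts higher and 667 lower after inoculation (4.4% of those tested), with medians of 3.61 and −1.72 (log2; 3.38 and −1.71 without those listed at 0 in a whole group). Quantile scaling gave 1283 higher and 1199 lower, so the excess of rises depended on the scaling. TraesCS5D02G488700.1 rose by 11.89 ± 1.06 (SE, n = 3 pots per group; limma, adjusted p = 3.1e-07), from 0.639 ± 1.11 (SD) to 7289 ± 4991. TraesCS5D02G488800.2, whose gene model is numbered next to it, was listed at 0 in mock and at 4127, 2066 and 1101 after inoculation (adjusted p = 6.5e-09). Both TraesCS2D02G423500.3 (adjusted p = 0.0012) and TraesCS2D02G423500.2 (adjusted p = 0.016) were listed at 0 in all 3 inoculated pots. In mock they were at 703, 482 and 965 and at 1076, 455 and 596, and the second lost its call under 6 of 20 alternatives. Of the rises at 96 h, 862 (72.3%) had been called at 48 h, with 104 expected, as had 428 of the falls (64.2%), with 56.1 expected. Fitted alone, these 6 libraries gave 2 calls, weights per library gave 7021 and the sets at 0 h as baseline 694. The count was 655, 3074 and 401 without mock replicates 1, 2 and 3 and 866, 745 and 1095 without Ptr replicates 1, 2 and 3. In mean log2 level of the shared rises, mock replicate 2 was at 4.44, against 2.04 and 2.12 in mock replicates 1 and 3.

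In Robigus at 96 h, 129 transcripts were higher and 7 were lower after inoculation. The rises had a median of 5.96 (log2; 6.04 without those listed at 0 in a whole group), and the same transcripts had 5.81 in Hereward at 96 h. Of these rises in Robigus, 52 (40.3%) were listed at 0 in all 3 mock pots. TraesCS5D02G488700.1 was again among the largest, listed at 0 in mock and at 953, 8856 and 4307 after inoculation (limma, adjusted p = 4.5e-07). TraesCS3B02G293200.1 was also listed at 0 in mock and at 339, 4199 and 1771 in inoculated pots (adjusted p = 1.2e-05). The isoforms TraesCS5A02G431200.2 (144, 160 and 178 in mock, limma, adjusted p = 0.043) and TraesCS1D02G292400.2 (164, 140 and 178, adjusted p = 0.032) were listed at 0 after inoculation, and lost their calls under 8 and 9 of 20 alternatives. In all groups but Robigus mock at 96 h, the means of TraesCS1D02G292400.2 were between 0 and 14 normalized counts. Its fall thus rests on a high mock group at that time alone, with a mean of 161. Of the rises, 104 (80.6%) had been called at 48 h in Robigus, with 0.9 expected, and 99 (76.7%) were called in Hereward at 96 h, with 3.64 expected. Of the 7 falls, 0 were called lower by limma at 48 h or in Hereward at 96 h (0.00546 and 0.11 expected; 3451 transcripts had an unadjusted p under 0.05 in Robigus at 96 h), and 4 (57.1%) were called when the transcripts of a gene model were summed. All 3 inoculated pots lay above all 3 mock pots for 11.6% of the transcripts and below for 10.7%, against 7.66% and 5.82% at 48 h and 5.09% and 4.65% between the Robigus sets at 0 h. These shares rose from 48 h to 96 h while the number called fell, and in Hereward at 96 h they were 13% and 11.6%. Pooled SDs within the Robigus groups were 1.67 (mock) and 2.08 (Ptr) at 48 h and 1.29 and 1.37 at 96 h. The tests at both times used the same estimate of the spread. There were 86 transcripts called higher in all 4 comparisons of inoculated with mock plants and 0 called lower in all 4 (limma), where 168 lay below mock in every pot of each comparison. Weights per library gave 904 calls and 397 shared rises at 96 h, and the sets at 0 h as baseline gave 12 and 10. Fitted alone, the Robigus libraries of 96 h gave a count within 1.5 times the 136 called. The count was 71, 76 and 64 without mock replicates 1, 2 and 3, 36 without Ptr replicate 2 and 83 without Ptr replicate 3.

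**Figure D3:**
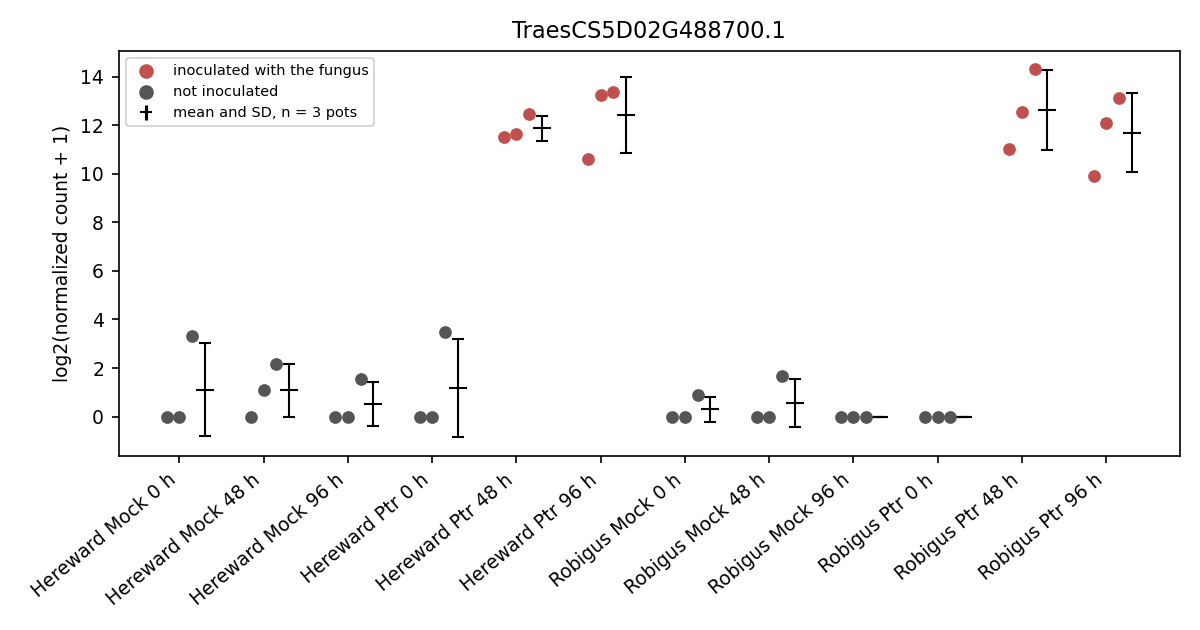
Log2(normalized count + 1) of TraesCS5D02G488700.1, 1 point per library, with the mean and SD of 3 pots per group. The Ptr groups at 48 h and 96 h lie far above the uninoculated groups, most of whose pots are listed at 0; the group means in normalized counts are 3912 and 7289 in Hereward and 9412 and 4705 in Robigus.

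The difference in response between the cultivars was tested directly. At 48 h no transcript passed (limma, 0 calls; smallest adjusted p = 0.226; 4421 at an unadjusted p under 0.05), so the larger number of calls in Hereward is not shown for any single transcript to be a larger response. The transcripts called higher in Hereward changed less in Robigus by a median difference of −1.14, and those called lower by 1.37, but such medians lean away from the cultivar in which the transcripts were selected. At 96 h, 4 transcripts differed (2637 at an unadjusted p under 0.05). TraesCS2B02G616700.1 (limma, adjusted p = 0.0448) and TraesCSU02G137300.1 (adjusted p = 0.0224) were listed at 0 in mock plants of both cultivars at 96 h. They reached 1004, 638 and 160 and 1110, 427 and 78 in inoculated Hereward, and were at 1.01 or below in inoculated Robigus at 96 h. In Robigus Ptr replicate 3 at 48 h they were at 22.8 and 10.1. Their values had the same order over the inoculated Hereward pots at both times. Reads shared between them, or reads of the fungus, were thus not told apart from separate rises in the plant. TraesCS1A02G402500.1 fell by 1.57 ± 0.27 (SE, n = 3) in Hereward (adjusted p = 0.00132) and had a change of 0.80 ± 0.27 in Robigus (adjusted p = 0.332). TraesCS3B02G091800.3 fell by 2.01 ± 0.28 in Hereward (adjusted p = 0.000111) and had a change of 0.27 ± 0.28 in Robigus (adjusted p = 0.869). Weights per library gave 387 transcripts at 48 h and 320 at 96 h, a fit without trend or robust step gave 2 and 8, and a fit of only the groups compared gave 1 at 96 h. At 96 h trimmed-mean scaling and the length correction each gave 2, and a replicate block gave 0. At 48 h there were 604 without Robigus Ptr replicate 3, 397 without Hereward Ptr replicate 2, 168 without Hereward mock replicate 1, 2 without Hereward Ptr replicate 1 and 1 without Robigus Ptr replicate 1. At 96 h there were 0 without Robigus mock replicate 2 or Robigus Ptr replicate 2, 1 without Hereward Ptr replicate 1, and 2 without Hereward mock replicate 3, Hereward Ptr replicate 3 or Robigus mock replicate 3.

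Between 48 h and 96 h the response itself changed for a single transcript in Hereward. TraesCS1A02G402500.1 rose by 0.93 ± 0.27 (SE, n = 3) at 48 h (limma, adjusted p = 0.019) and was lower than mock by 96 h, a difference of −2.50 ± 0.38 between the times (adjusted p = 0.0229). Its means were 428 ± 57.8 (SD) in inoculated and 226 ± 45.5 in mock pots at 48 h, and 81.3 ± 13.1 and 244 ± 45.5 at 96 h. There were 2791 transcripts with an unadjusted p under 0.05 in this test. In Robigus 0 transcripts passed (limma; smallest adjusted p = 0.0751; 1010 at an unadjusted p under 0.05). The shared rises were at 7.91 ± 0.82 in inoculated Hereward and 6.75 ± 1.20 in inoculated Robigus at 96 h, against 2.87 ± 1.36 and 2.31 ± 0.163 in mock. A lower level than at 48 h can follow from their choice at 48 h. The Hereward mock mean at 96 h includes replicate 2 at 4.44, against 2.04 and 2.12 in replicates 1 and 3. With weights per library 1211 transcripts passed in Hereward, and with quantile scaling 2. A fit of only the groups compared and a replicate block each gave 0 there. Without single libraries the Hereward count was 78 (mock 48 h replicate 1), 24 (Ptr 48 h replicate 2), 7 (Ptr 96 h replicate 1), 6 (mock 96 h replicate 1), 3 (Ptr 48 h replicate 1), 2 (mock 48 h replicate 2 or Ptr 96 h replicate 2) or 0 (Ptr 48 h replicate 3, mock 96 h replicate 3 or Ptr 96 h replicate 3). The Robigus count was 16 without Ptr 48 h replicate 3 and at most 1 without any other library.

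Before treatment the cultivars differed in 5.5% of transcripts, with 1294 higher and 1030 lower in Robigus than in Hereward (medians 2.56 and −1.77, log2, or 2.07 and −1.46 without those listed at 0 in a whole group; 6 pots per cultivar). TraesCS7B02G459600.1 was higher in Robigus (limma, adjusted p = 3.2e-07), with means of 2758 ± 564 and 2503 ± 334 (SD, n = 3) in the mock and Ptr sets of Robigus and a single nonzero value of 21 in the 6 Hereward pots. TraesCS5A02G014400.2 was at 1009 to 2292 in the 6 Robigus pots and listed at 0 in all 18 Hereward libraries (adjusted p = 2.2e-20). TraesCS1B02G459100.1 was lower in Robigus than in Hereward by 11.69 ± 0.46 (limma, adjusted p = 9.1e-17), with 8329 ± 2735 and 3544 ± 1920 in the Hereward sets and means of 0.334 ± 0.579 and 1.09 ± 1.12 in the Robigus sets. TraesCS2B02G427900.1 was at 1114 to 4370 in Hereward and listed at 0 in the 6 Robigus pots (adjusted p = 1.1e-16). The difference mostly kept its sign in later mock plants. At 48 h 89.5% of the transcripts higher in Robigus at 0 h and 89.7% of the lower ones did so, and 79.6% and 83.1% did at 96 h. Their medians were 1.47 and −1.25 at 48 h and 1.16 and −1.04 at 96 h, smaller than at 0 h, where the transcripts were selected. The difference at 0 h was uneven over the genome, with 8.44% of transcripts called on chromosome 2B, 8.31% on 7A and 7.78% on 3B against 3.28% on 1D and 3.42% on 1A. The share was 13.4% among the 476 transcripts on unplaced sequence. By subgenome, 3.82% were higher and 2.77% lower on B against 2.27% and 1.71% on D. Over all times, 75 transcripts were at 10 or more in at least 15 of the 18 Robigus libraries and listed at 0 in all 18 Hereward ones, and 28 showed the reverse. Of these, 33 and 15 lay on the B subgenome. The reference transcripts were not given, so whether reads of both cultivars matched them equally well was not tested. The Hereward sets differed from each other at 0 h. Compared over the mock sets alone, which leaves 3 pots per cultivar, 582 transcripts were higher and 497 lower in Robigus, 514 and 415 of them among those above, and 3.83% were called on 2B. There, 93.1% of the transcripts called higher over both sets and 98.3% of those called lower had the same sign. A fit of the 0 h groups alone called 3665 transcripts and weights per library 6882, and quantile scaling turned the balance to 1149 higher and 1327 lower.

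**Figure D4:**
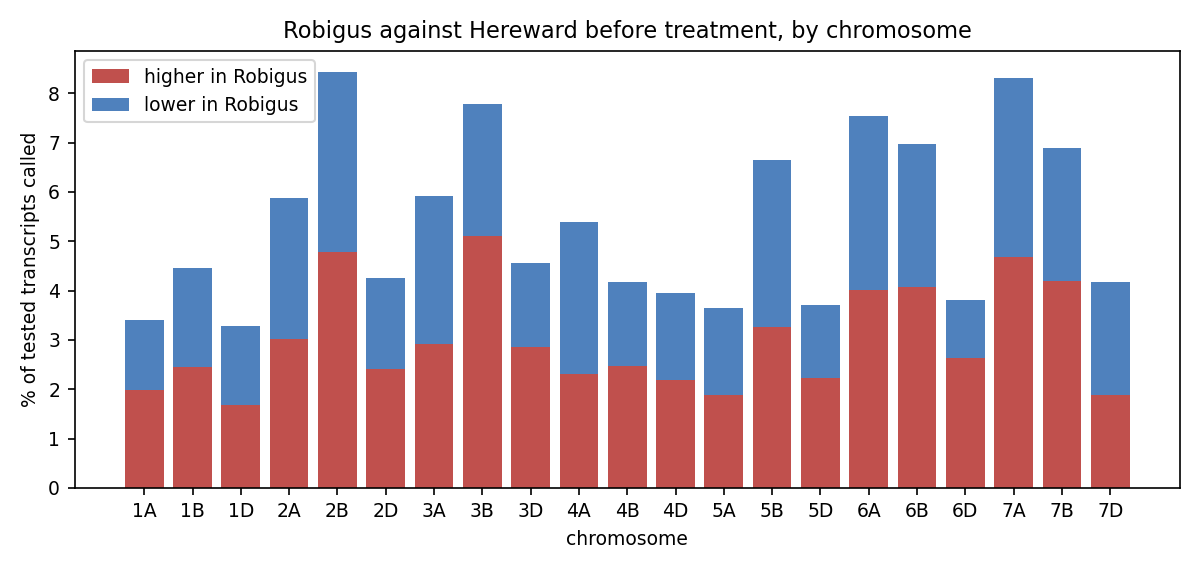
Percent of tested transcripts per chromosome called higher (red) or lower (blue, stacked) in Robigus than in Hereward at 0 h, 6 pots per cultivar. Unplaced sequence, at 13.4%, is not drawn; among the chromosomes the tallest bar is 2B at 8.44% and the lowest 1D at 3.28%.

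The Ptr and mock sets were both untreated at 0 h, so their comparison measures how alike the sets were at the start. In Robigus 1 transcript differed (limma; 1168 at an unadjusted p under 0.05): TraesCS2A02G113900.2 was listed at 0 in the mock set and at 516, 142 and 518 in the Ptr set (adjusted p = 2e-07), and no gene model was called when transcripts were summed (limma, 0). In Hereward 1609 transcripts differed, 466 higher and 1143 lower in the Ptr set, with medians of 1.88 and −2.17 (log2; 1.87 and −2.12 without those listed at 0 in a whole group). TraesCS2D02G254400.1 (391, 394 and 370 in the Ptr set; adjusted p = 0.041) and TraesCS7B02G025700.3 (277, 221 and 148; adjusted p = 0.012) were listed at 0 in the mock set. TraesCS5B02G022800.4 (1322, 2325 and 3411 in the mock set; adjusted p = 0.028) and TraesCS5B02G336100.1 (3719, 362 and 2720; adjusted p = 0.001) were listed at 0 in the Ptr set. The calls of the first 3 were lost under 7, 3 and 7 of 19 alternatives. Comparisons of inoculated with mock Hereward thus start from sets that were not alike. Across transcripts the set difference had a Pearson r of −0.03 with the Hereward response at 48 h and 0.28 with that at 96 h. It had the same sign as 46.4% of the rises and 53.3% of the falls at 48 h, and as 68.6% and 72.1% at 96 h, so the 96 h calls lean toward it. Robigus, measured in other pots, had r of 0.09 at 48 h and 0.28 at 96 h. The sign was shared by 70.8% of the Robigus rises and 57.6% of the falls at 48 h, and by 74.4% and 100% at 96 h. The lean is thus not particular to Hereward and alone does not show that its starting sets entered the 96 h calls. The Hereward count was 539 in a fit of these 6 libraries alone and 6381 with weights per library, and 498 without mock replicate 1, 761 without mock replicate 3 and 811 without Ptr replicate 1. The Robigus count was 858 with weights per library, 0 in a fit of its 6 libraries alone, 14 without Ptr replicate 2 and 5 without mock replicate 3.

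In mock plants of both cultivars 2796 transcripts were higher and 3677 lower at 48 h than at 0 h, with medians of 1.45 and −1.43 (log2; 1.38 and −1.39 without those listed at 0 in a whole group). At 96 h 2184 were higher and 2302 lower than at 0 h, with medians of 1.46 and −1.36 (1.44 and −1.31). TraesCS5D02G068800.1 rose by 7.55 ± 0.49 at 48 h (SE, n = 6 pots per time; limma, adjusted p = 1.4e-10) and by 7.19 ± 0.49 at 96 h (adjusted p = 2.7e-10), from 5.38 ± 1.35 (SD, n = 3) in Hereward and 5.88 ± 3.18 in Robigus to 930 ± 774 and 1928 ± 169 at 48 h. TraesCS5A02G057500.2 was higher at 48 h (adjusted p = 2.5e-07), listed at 0 in 5 of the 6 mock pots at 0 h and at 293, 772 and 395 in Hereward and 1082, 700 and 1174 in Robigus at 48 h. The Hereward Ptr set, untreated at 0 h, already had 364, 187 and 157 of TraesCS5A02G057500.2. TraesCS3D02G480100.1 rose by 7.07 ± 0.61 at 96 h (adjusted p = 1e-08). TraesCS4A02G097900.2 fell by 9.04 ± 1.55 at 48 h (adjusted p = 2e-04), from 11464 ± 2575 in Hereward and 8991 ± 2720 in Robigus. TraesCS6B02G346700.2 fell by 8.03 ± 0.70 at 96 h (adjusted p = 1.2e-08), from 4958 ± 3410 and 1651 ± 596 to 13.6 ± 12 and 12.3 ± 5.67. TraesCS5B02G022800.4 was listed at 0 in all 6 mock pots at 48 h (adjusted p = 0.0023), and TraesCS6D02G017100.3 in all 6 at 96 h (adjusted p = 4.2e-05). Both contrasts use the same 0 h libraries, so their overlap is not given. Weights per library raised the counts to 16878 at 48 h and 9385 at 96 h. Quantile scaling turned the balance to 3184 higher and 3123 lower at 48 h and to 2466 and 2028 at 96 h.

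**Figure D5:**
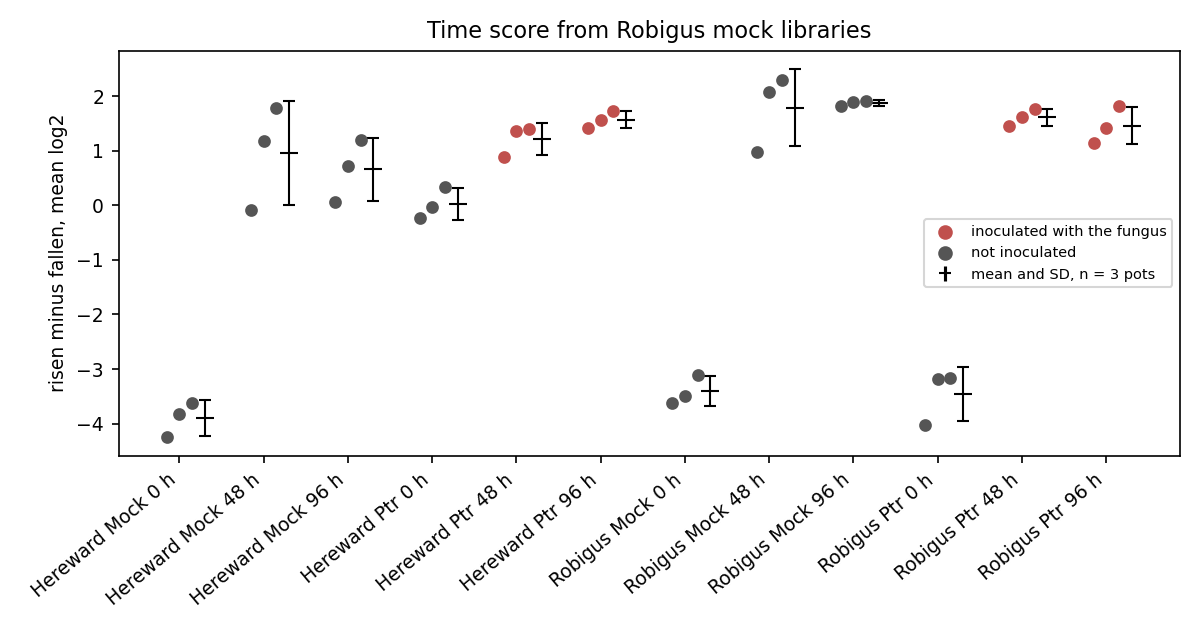
Mean log2 level of transcripts that rose minus that of transcripts that fell with time in Robigus mock plants, 1 point per library, with the mean and SD of 3 pots per group. Hereward Ptr plants at 0 h lie between −0.24 and 0.34, above the Hereward mock plants at 0 h (−4.25 to −3.62) and below or beside the later groups.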

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

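The counts over other splits of the libraries were planned before their results were seen. The tests of the spread between Robigus pots and of single libraries were chosen after the gap between the cultivars was seen.

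A transcript drew attention where its response differed between the cultivars or between the times in a test of that difference itself. At 96 h the fitted response (inoculated minus mock, Robigus minus Hereward) differed by −8.39 (log2) for TraesCSU02G137300.1 and by −8.54 for TraesCS2B02G616700.1. Both were listed at 0 in all mock pots at 96 h, so these sizes depend on the pseudocount and are no bounds. For TraesCS1A02G402500.1 it differed by 2.37 ± 0.38 (SE) and for TraesCS3B02G091800.3 by 2.27 ± 0.39. TraesCS1A02G402500.1 also differed between 96 h and 48 h in Hereward, by −2.50 ± 0.38. Over 25 alternatives the calls at 96 h were lost under 5 for TraesCSU02G137300.1, 10 for TraesCS1A02G402500.1, 13 for TraesCS3B02G091800.3 and 16 for TraesCS2B02G616700.1, with adjusted p up to 0.37, 0.48, 0.37 and 0.37 (limma). The call between times in Hereward was lost under 6 of 25, with an adjusted p up to 0.77. In each of these alternatives the change kept its sign.

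Chance is not excluded for the transcripts that differed. Of 100 splits drawn from those of the same libraries, 11 called at least the 4 transcripts found for the cultivar difference at 96 h, and 57 at least the 1 found between the times in Hereward. The highest counts of other splits, 1959 and 10049, came from splits that exchange whole inoculated and mock groups and so carry the effect of inoculation, a structure of these samples. Splits that mix the pots of only 1 cultivar or 1 time carry it too. The 11 and 57 of 100 are thus no rates under chance alone and do not decide the question. For the cultivar difference at 48 h and the difference between times in Robigus, where 0 transcripts were called by limma (4421 and 1010 at an unadjusted p under 0.05), all 100 splits called at least as many by construction, so the splits decide nothing there. Their highest counts were 7273 and 182.

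Inoculation at 48 h gave 22.1 times as many called transcripts in Hereward as in Robigus, 7255 against 328. Against a single library as the whole cause, the ratio stayed at 3.76 or above whichever of the 12 libraries was left out. A larger spread between the Robigus pots (pooled SD within the 48 h groups 1.09 times that of Hereward) cannot act through the standard error, which shares 1 estimate of the spread and had a median of 0.593 in both cultivars. Whether scattered pots blurred the Robigus means is not decided. Transcripts called higher in Hereward at 96 h had median changes at 48 h, over the 9 pairs of an inoculated and a mock pot, of 1.27 to 3.87 in Hereward and 0.79 to 2.66 in Robigus, and these ranges overlap. Without Robigus Ptr replicate 3 the Robigus count rose to 1928. A difference in response between the cultivars is also open: limma called 0 transcripts for it at 48 h (4421 at an unadjusted p under 0.05). The 10 splits of 6 libraries are too few for a share under 0.05 in either cultivar: the real split was the 1 with most calls, with 2133 in the next for Hereward and 108 for Robigus. At 96 h the same held, with 1860 against 230 in Hereward and 136 against 0 in Robigus (limma).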

How the results depend on the processing

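The values summed per gene model, the length correction, the baseline at 0 h and the mock sets alone were chosen after the data were seen; the other alternatives were fixed before. Of 337 values (counts and the share called on 2B) under alternatives, 233 stayed within 1.5 times the reported one and 104 did not. For named transcripts 719 of 844 calls held, 125 were lost and 0 changed sign. These totals, and the numbers of alternatives given per transcript, include repeats with other filters, which could not change a result. For named transcripts the minimum change of 1 could not change a call either. The cause of each shift below was not tested, unless stated. Weights per library called 13249 (Hereward 48 h), 7021 (Hereward 96 h), 184 (Robigus 48 h), 904 (Robigus 96 h), 387 and 320 (cultivar difference at 48 h and 96 h), 1211 (Hereward between times), 6882 (cultivars at 0 h), 6381 and 858 (Hereward and Robigus sets at 0 h), 16878 and 9385 (mock 48 h and 96 h), with 143 and 397 shared rises. A fit of only the groups compared takes the spread from those groups alone, with fewer libraries. It called 70 (Hereward 48 h), 2 (Hereward 96 h), 0 (Robigus 48 h), 1 (cultivar difference 96 h), 0 and 1 (Hereward and Robigus between times), 3665 (cultivars), 539 and 0 (Hereward and Robigus sets). It moved no other count by over 1.5 times, so Robigus at 96 h stayed within that of its 136 calls. Hereward at 96 h fell from 1860 to 2. The cultivar count rose from 2324, so fewer libraries alone do not account for these shifts. The baseline at 0 h called 4400 and 694 in Hereward, 43 and 12 in Robigus, with 34 and 10 shared rises. Its standard errors are larger, so calls drop even where the sets were alike. In Robigus, whose sets differed in 1 transcript, the count at 48 h went from 328 to 43. The cultivars compared over the mock sets alone, with fewer pots, gave 1079 calls and 3.83% on 2B. For small counts, pseudocount 0.5 gave 1 (Robigus between times), pseudocount 5 gave 2 (cultivar difference 48 h), FPKM values gave 1 and 1 (the same contrasts), trimmed-mean scaling 2 (cultivar difference 96 h), quantile scaling 2 (Hereward between times), the model without trend or robust step 2 and 8 (cultivar difference 48 h and 96 h), 1 (Robigus between times) and 2 (Robigus sets), sums per gene model 1 (Robigus between times) and 0 (Robigus sets), and the length correction 2 (cultivar difference 96 h). Quantile scaling moved the share of rises in Hereward at 96 h from 64.1% to 51.7% and between the Hereward sets from 29% to 40.2%, and turned the majority for Hereward 48 h (51% to 47.3%), the cultivars (55.7% to 46.4%) and mock 48 h (43.2% to 50.5%) and 96 h (48.7% to 54.9%). Near-even balances also turned under trimmed-mean scaling and the length correction for Hereward 48 h (49.9%, 48.5%) and mock 96 h (52.5%, 51.6%), for mock 96 h with a minimum change of 1 (51.7%), and, without 1 library, for Hereward 48 h (46.1% to 47.4%) and mock 96 h (50.1% to 52.9%). For Robigus 48 h the share of rises went from 89.9% to 46.2% and 23.5% without Ptr replicates 2 and 3.

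Without 1 library the counts ran from 1929 to 10600 (Hereward 48 h), 401 to 3074 (Hereward 96 h), 118 to 1928 (Robigus 48 h), 36 to 144 (Robigus 96 h), 0 to 604 and 0 to 6 (cultivar difference 48 h and 96 h), 0 to 78 and 0 to 16 (Hereward and Robigus between times), 1819 to 2428 (cultivars), 498 to 1823 and 1 to 14 (Hereward and Robigus sets), 4415 to 9527 and 3306 to 4510 (mock 48 h and 96 h). No clear pairing of Ptr with mock pots by replicate number was seen: correlations of same-numbered pots within a time ran from −0.48 to 0.28, 7 of 18 were above 0.1, and a pot correlated best with its own number in 9. At 0 h all 3 Hereward pots did so, at 0.05, 0.21 and 0.2 against at most 0.03, −0.1 and 0.04 with other numbers. Robigus replicates 2 and 3 did too and replicate 1 did not, so pairing at 0 h is not excluded. Between times of a set, correlations of same-numbered pots ran from −0.65 to 0.35. All 3 were above 0.1 only for Hereward Ptr at 0 h and 48 h (0.16 to 0.35). Only the repeat with the sets at 0 h as baseline compares these groups, and it was fitted without pairing. A replicate block called 1080 (Hereward 96 h), 143 and 31 (Robigus 48 h and 96 h), 0 (cultivar difference 96 h), 0 (Hereward between times) and 942 (Hereward sets), with 120 and 26 shared rises, and moved no other count by over 1.5 times. Count models were not run, as no counts were recovered, and the gene lists could not be tested. The filters removed 0 transcripts and test nothing.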

Other observations

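The neighbour counts, the counts by abundance and the time score were chosen after the calls were seen, as were the tests on the shared rises and on the Hereward sets, except the exchange with a later group, which was planned before its result was seen. The counts over other splits were planned before their results were seen.

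Transcripts that rose after inoculation sat next to one another on the chromosomes more often than random sets did. Gene model numbers follow the order along a chromosome, and 63 of the 254 placed models among the shared rises (24.8%) had another member within 5 numbers. The median of 1000 random sets of the same size was 2.36% and the highest 8.27%. For the rises of Robigus at 96 h the share was 32%, against a median of 1.64%. In the larger Hereward sets the excess was smaller, with 37.6% against 31.8% (highest 35%) at 48 h and 21% against 12% (highest 15.3%) at 96 h. The longest runs were on chromosome 5D, where 7 of 8 tested models around TraesCS5D02G488700.1 rose in both cultivars at 48 h, and on 2D, where 6 of 7 did. On 2B all 4 tested models of a run rose. The differences between cultivars at 0 h also clustered, with 24.7% of the higher and 20.4% of the lower models having such a neighbour, against random medians of 13.1% and 10.4%. Reads shared between neighbouring copies would add to these shares, and that was not tested.

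The most abundant transcripts mostly fell in Hereward. Of the 422 transcripts in the top 1% by mean level, 239 fell and 3 rose in Hereward at 48 h, with a median change of −2.42, and 91.7% of them were negative. At 96 h 21 fell and 1 rose, with a median of −1.37. In Robigus 0 of them were called lower by limma at either time (5995 and 3451 of all transcripts had an unadjusted p under 0.05 at 48 h and 96 h), and 1 was called higher at 48 h. Of all 422, called or not, 92.4% were negative at 48 h, with a median of −0.93, and 80.6% at 96 h, with a median of −0.32. Between the sets at 0 h the medians were −0.13 in Hereward and 0 in Robigus. The lower sums of normalized counts in inoculated plants go with this fall. Within gene models, 14 of the 563 with more than 1 transcript and a call in Hereward at 48 h had transcripts called in opposite directions, and 15 of 217 did between the cultivars at 0 h.

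The shared rises were chosen at 48 h, so the 96 h libraries, which were not used, test whether they were picked by chance: 99.3% of them had group means above mock in both cultivars at 96 h, which argues against that. For the submitters' scaling, the median change of all transcripts in Robigus at 48 h was −0.08. These medians lay between −0.15 and 0.08 in every contrast, as scaling to a common level would give, so this value does not test the scaling. Quantile scaling left 216 shared rises at 48 h. Another candidate explanation is that reads of the fungus were assigned to wheat transcripts. Of the members, 53.2% were at 10 or more in at least 3 of the 24 uninoculated libraries and 31 were at 0 in all 6 mock pots at 48 h, which does not settle where the added reads come from, so a rise in the plant and fungal reads cannot be told apart here. In their mean log2 level, Hereward mock replicate 2 at 96 h, with 4.44, Hereward Ptr replicate 3 at 0 h, with 3.44, and Robigus mock replicate 2 at 48 h, with 3.32, were the highest uninoculated libraries.

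The sets of untreated Hereward plants differed at 0 h in 1609 transcripts, and the next highest count among the 10 splits was 181, too few splits for a share under 0.05. For Robigus, 4 of the 10 splits called at least 1 transcript. A single library out of place is argued against, since 487 or more of the 1609 stayed called with any of the 6 left out. An exchange of these plants with a later Hereward group is argued against by the time score, since 12 of 12 later Hereward libraries scored above the highest Hereward mock plant at 0 h and none was free to be the partner. The Hereward difference correlated across transcripts, which are not independent replicates, with the change of Robigus mock plants from 0 h to 48 h at a Pearson r of 0.59, and 94.8% of the transcripts higher and 95.4% of those lower in the Ptr set went the same way there. These plants may thus have been in a state that other plants reached later, by a difference in sampling, age or handling that the labels do not record. An example is TraesCS4A02G097900.2, at 11464 ± 2575 (SD, n = 3) in the Hereward mock set, 176 ± 126 in the Ptr set, and 264 ± 457 in Hereward mock plants at 48 h. It was picked for its fall in mock plants, a contrast that uses the same mock libraries at 0 h, so it is no separate test.

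The cultivar and time contrasts stood apart from other splits. The real split was the 1 of 100 drawn with the most calls for Robigus against Hereward at 0 h (2324, highest other 543), for mock plants at 48 h against 0 h (6473, highest other 3337) and at 96 h against 0 h (4486, highest other 861), which argues against chance for these 3 contrasts.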
